A study of Mus musculus with 12 samples.

How the data were processed

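Bone marrow of wild-type 129S1/J mice was cultured with GM-CSF at 20 ng/ml, per the labels' protocols, and 100000 of the resulting cells were plated per well in 140 µl with 60 µl of broth or spent medium and no further GM-CSF. From each well 1000 cells were collected for Smart-seq, a full-length method that copies polyadenylated RNA, with 18 cycles of PCR and 38-bp paired reads. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.7.3a and counted with featureCounts of Subread 2.0.0. The annotation version, the strand setting and the handling of reads that map to several places are not given in the sources used here. The deposited values are raw counts per gene symbol for the 12 libraries, whole numbers with no normalization by the authors.

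From the deposited counts, genes with enough counts were kept by filterByExpr with the 4 groups, which left 11726 of 55011 symbols and 98.2% to 99.4% of the counts of each library. Of the tested symbols 11576 matched the gene name table, and 2 list members were looked up under another symbol. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were not analysed here. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test over all 12 libraries with 4 group means, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.0976. CPM values are TMM-scaled, given as mean ± SD over 3 libraries, and log2 fold changes carry their standard error. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

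The comparisons were zymosan against broth, ASF519 against broth, ASF519 with zymosan against zymosan, ASF519 with zymosan against ASF519, and the interaction of both treatments. The design, the alternatives, the gene lists, a panel of 23 genes and the rule for named genes were fixed before the data were examined. The rule takes, per comparison of 2 groups, the 10 largest rises and falls among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups' libraries, leaving out predicted genes. For the interaction it takes the 5 largest values of each sign with the same expression minimum. It adds the 2 largest changes of each sign past the threshold in each gene list, and any gene of the panel. Of the genes this rule takes, 1 was left out and is not reported here.

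Gene lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry, with adjustment over lists within a comparison. Where a list past the threshold is given with no second p, its call holds with an estimated correlation as well, but at a larger p. For inflammatory cytokines with zymosan in broth this was 1.92e-04 against 1.18e-25. Of 32 lists, 21 held functions, covering inflammatory cytokines, chemokines, maturation, MHC classes I and II, interferon-stimulated genes, NF-kB targets and immediate early genes. Pattern recognition, regulation, inflammasome, eicosanoids, antioxidants, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, lipid targets, lysosome, endoplasmic reticulum stress, cell cycle and matrix made up the rest of these. Another 2 held ribosomal proteins and mitochondrially encoded genes as signs of RNA quality. The last 9 held markers of dendritic cells, macrophages, monocytes, neutrophils, mast cells or basophils, eosinophils, T and NK cells, B and plasma cells, and erythroid cells. Members counted as rising or falling passed the threshold over all tested genes, and beside this stands the number adjusted over the list alone.

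Alternatives were DESeq2 1.42.0, limma-voom, other scaling, no filter or one of at least 5 CPM in at least 3 libraries, counts thinned to the smallest total, a block for replicate number, fits of the compared groups alone and fits without each library in turn. After the data had been seen, fits without symbols with satellite-like reads, with protein-coding genes alone and with the background expected from unused gene families subtracted were added. That background was taken per kb of exon from 1625 genes of receptor and structural families. Gene positions and exons came from GENCODE M21 for mm10. For a gene with 1 to 3 counts in a group the ratio is given with its 95% counting interval, and for a group at 0 the fold is a lower bound against 3 counts over the group. Intervals and floors cover counting error only, since PCR copies without molecular identifiers are not independent molecules.

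No pair of libraries in a group was alike within sampling noise, with a chi-square per degree of freedom of 2.22 to 8.97, and correlations of log2 CPM were 0.967 to 0.984 within groups and 0.918 to 0.974 between them. The steps were tested on simulated counts drawn from the real broth means and library sizes. Every group had the broth means apart from planted changes, so the large effects of zymosan and spent medium were absent. For ASF519 against broth, over 11029 genes, edgeR recovered 35.9% of genes changed 1.5-fold, 68.2% at 2-fold and 94.9% at 4-fold, and 8 of 132 calls were false. For the interaction, over 11011 genes, it recovered 9.52%, 45.5% and 81.0%, and 10 of 93 calls were false. The list test recovered the planted list and called 1 other of 27.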

Results

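RNA was measured by Smart-seq in dendritic cells grown from the bone marrow of wild-type 129S1/J mice with GM-CSF, a growth factor that turns marrow precursors into dendritic cells and macrophages. ASF519 is a gut bacterium of the altered Schaedler flora, a defined community of mouse commensals, and is known as Parabacteroides goldsteinii. Zymosan is a yeast cell wall particle rich in beta-glucan, sensed through dectin-1 and Toll-like receptor 2. Cells were kept in plain bacterial broth or in medium spent by ASF519 for 40 h, and zymosan at 4 µg/ml then followed for 16 h in some of the wells. This gave 4 groups of 3 libraries, called here broth, zymosan, ASF519 and ASF519 with zymosan. Total counts per library ran from 2333814 to 5022807 over 55011 gene symbols, of which 11726 had enough counts to be tested. Per group the totals were 2892592 to 3446681 in broth, 4050705 to 5022807 with zymosan, 2333814 to 3853188 in ASF519 and 2853456 to 3726654 in ASF519 with zymosan. The first principal component, with 44.0% of the variance, separated the spent medium libraries from the others, and the second, with 17.0%, those with zymosan from those without. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The labels also leave open whether cells without zymosan were collected at 40 h or together with the zymosan-exposed cells 16 h later, so time in culture may enter each zymosan comparison.

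Reads in gene families that these cells do not use differed between the media. Olfactory, vomeronasal, trace amine and bitter taste receptors, keratin-associated proteins and defensins together took 414 ± 118 CPM (counts scaled by library size, mean ± SD, n = 3) in broth and 279 ± 15.5 with zymosan. The same families took 1517 ± 466 CPM in ASF519 and 976 ± 85.0 in ASF519 with zymosan. The number of genes with a count, after thinning all libraries to the smallest total, was 20369 ± 927 in broth and 26269 ± 2121 in ASF519. This background was expected to make up over 25% of the counts of 261 of the 1668 genes that rose in ASF519 against broth, a share limit set after the data had been seen. Of the 747 genes that rose at least 2-fold, 253 were over this limit.

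**Figure D1:**
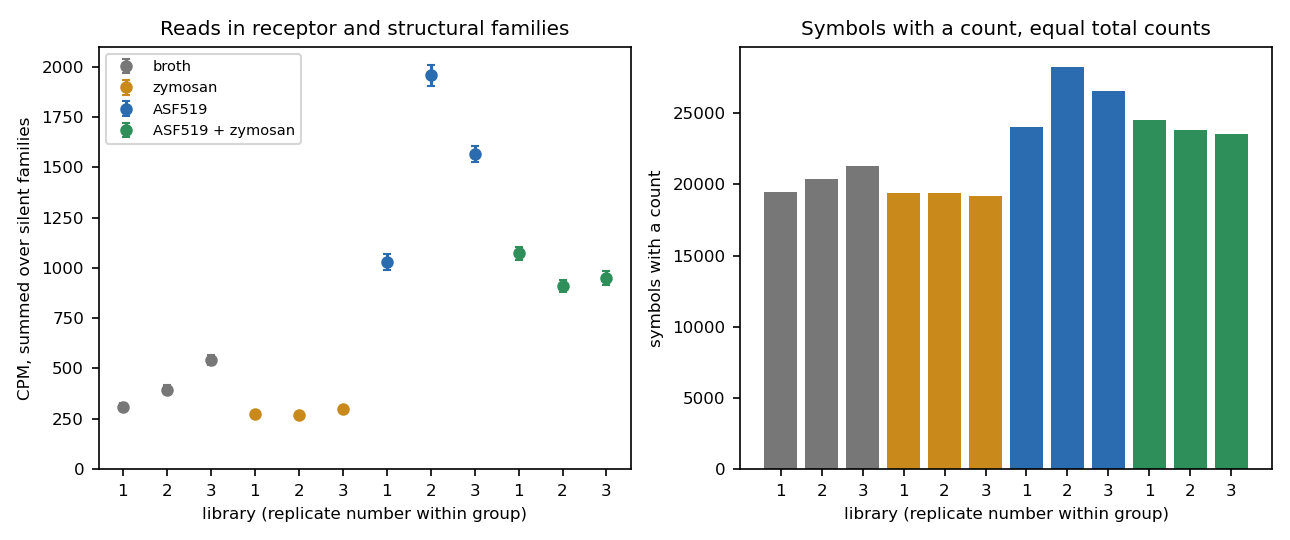
CPM in receptor and structural families that these cells do not use (left, with 95% counting intervals) and number of gene symbols with a count after thinning to equal total counts (right), for each of the 12 libraries by group and replicate number. The lowest spent medium library is at 1.68 times the highest of the other libraries on the left.

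Zymosan against broth shows what the yeast particle changed in cells kept in plain broth. The acute-phase gene Saa3 rose from 211 ± 15.0 to 5185 ± 1055 CPM (n = 3), and Lcn2, which encodes an iron-withholding lipocalin, from 83.1 ± 12.2 to 2011 ± 130.4 CPM. The inflammatory cytokine genes Il1b, Il1a, Tnf and Il6 rose by log2 2.38 ± 0.09 (SE), 2.96 ± 0.12, 1.70 ± 0.17 and 1.26 ± 0.10. Il12b, the p40 chain shared by IL-12 and IL-23, rose from 1234 ± 159 to 2612 ± 93.0 CPM, and Il23a, the p19 chain of IL-23, from 1.42 ± 0.942 to 11.5 ± 0.544 CPM. The complement genes C1qa and C1qb fell, at log2 -2.83 ± 0.11 and -2.29 ± 0.09, and the lipoprotein gene Apoe fell by 3.74 ± 0.19 on the log2 scale.

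In edgeR's quasi-likelihood test 1699 genes passed an adjusted p of 0.05, 924 higher and 775 lower with zymosan, and 506 of them changed at least 2-fold. Large rises were also seen for Vnn3 (log2 4.55 ± 0.52), Susd2 (4.43 ± 0.33), the collagen-crosslinking oxidase Lox (4.31 ± 0.14), the caveola protein Cav1 (4.12 ± 0.16) and the prostaglandin E synthase Ptges (3.89 ± 0.20). U90926 went from 1 count over the 3 broth libraries to 416 over the 3 zymosan libraries, a ratio of 297 (95% counting interval 53.1 to 11773). Il12a, the p35 chain of IL-12, likewise went from 1 count to 118, a ratio of 84.3 (95% counting interval 14.8 to 3359). The largest falls included the endosomal sodium-proton exchanger Slc9a9 (log2 -4.95 ± 0.29), the chemokine receptor Ccr2 (-2.92 ± 0.21) and the complement receptor C3ar1 (-2.82 ± 0.09). The costimulatory genes Cd40, Cd80 and Cd86 rose by 1.03 ± 0.08, 0.87 ± 0.12 and 0.88 ± 0.09, and Acod1, which makes itaconate, by 2.91 ± 0.09. Nos2, the inducible nitric oxide synthase, rose by 3.18 ± 0.43 and the pattern receptor Tlr2 by 1.44 ± 0.11. Arg1, which degrades arginine, fell by 1.40 ± 0.10, and Clec7a, which encodes dectin-1, fell by 0.64 ± 0.14. Il10, an anti-inflammatory cytokine, was at 0.535 ± 0.474 CPM in broth and 1.92 ± 0.727 CPM with zymosan and did not pass (adjusted p = 0.0799).

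Of 18 tested inflammatory cytokine genes 12 rose and 0 fell, with 13 up and 0 down adjusted over the list alone (camera, adjusted p = 1.18e-25). Csf3, the granulocyte growth factor, had 0 counts in broth and 24 with zymosan, at least 5.72-fold higher against a floor of 3 counts over the group. Among 16 chemokines 12 rose, Cxcl10 by log2 4.34 ± 0.52 and Ccl4 by 2.81 ± 0.38, and 2 fell, with Ccl6 at -2.04 ± 0.24 and Ccl9 at -1.34 ± 0.12 (adjusted p = 1.30e-21). They were 12 up and 3 down adjusted over the list alone. NF-kB targets and feedback inhibitors rose in 16 of 21 cases and fell in 0, Nfkbiz by 1.33 ± 0.12 and Zc3h12a by 1.11 ± 0.21 (adjusted p = 1.02e-13, 18 up and 0 down adjusted over the list alone). The inflammasome list had 4 rises and 2 falls among 17 genes (adjusted p = 4.04e-04, 6 up and 2 down adjusted over the list alone). Pattern recognition genes went both ways, 8 up and 7 down of 25, with the C-type lectin Clec4e at log2 2.81 ± 0.12 and the mannose receptor Mrc1 at -2.93 ± 0.33 (adjusted p = 9.63e-04, 8 up and 8 down adjusted over the list alone). Dendritic cell maturation genes rose in 10 of 21 cases and fell in 1 (adjusted p = 3.03e-05 and adjusted p = 0.147 with an estimated correlation). That list had 11 up and 2 down adjusted over the list alone. Interferon-stimulated genes rose in 11 of 33 cases and fell in 1, Ifit1 by 1.77 ± 0.31 and Isg15 by 1.69 ± 0.22 (adjusted p = 0.00133 and adjusted p = 0.319 with an estimated correlation). The interferon-stimulated genes were 11 up and 1 down adjusted over the list alone. Antioxidant genes rose in 12 of 20 cases and fell in 1, the cystine transporter Slc7a11 by 1.35 ± 0.08 (adjusted p = 1.40e-07 and adjusted p = 0.0890 with an estimated correlation). The antioxidant list had 16 up and 1 down adjusted over the list alone.

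Lysosomal genes fell in 13 of 28 cases and rose in 0, the proton pump subunit Atp6v0d2 being at log2 -1.28 ± 0.10 (adjusted p = 9.28e-09 and adjusted p = 0.136 with an estimated correlation). The lysosomal list had 2 up and 14 down adjusted over the list alone. Class II genes fell in 4 of 14 cases and rose in 0 (adjusted p = 0.00904 and adjusted p = 0.319 with an estimated correlation). They were 2 up and 5 down adjusted over the list alone. Of 21 LXR and PPAR-gamma target genes 9 fell and 2 rose, among the latter Acsl1 (2.48 ± 0.12), an acyl-CoA synthetase (adjusted p = 9.63e-04, 3 up and 10 down adjusted over the list alone). Macrophage markers fell in 11 of 17 cases and rose in 3 (adjusted p = 3.25e-10, 4 up and 11 down adjusted over the list alone). Neutrophil-associated genes rose in 4 of 9 cases, Camp by 3.50 ± 0.29 beside Lcn2, and 1, Padi4, fell by 2.94 ± 0.56 (adjusted p = 1.26e-11, 4 up and 3 down adjusted over the list alone).

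**Figure D2:**
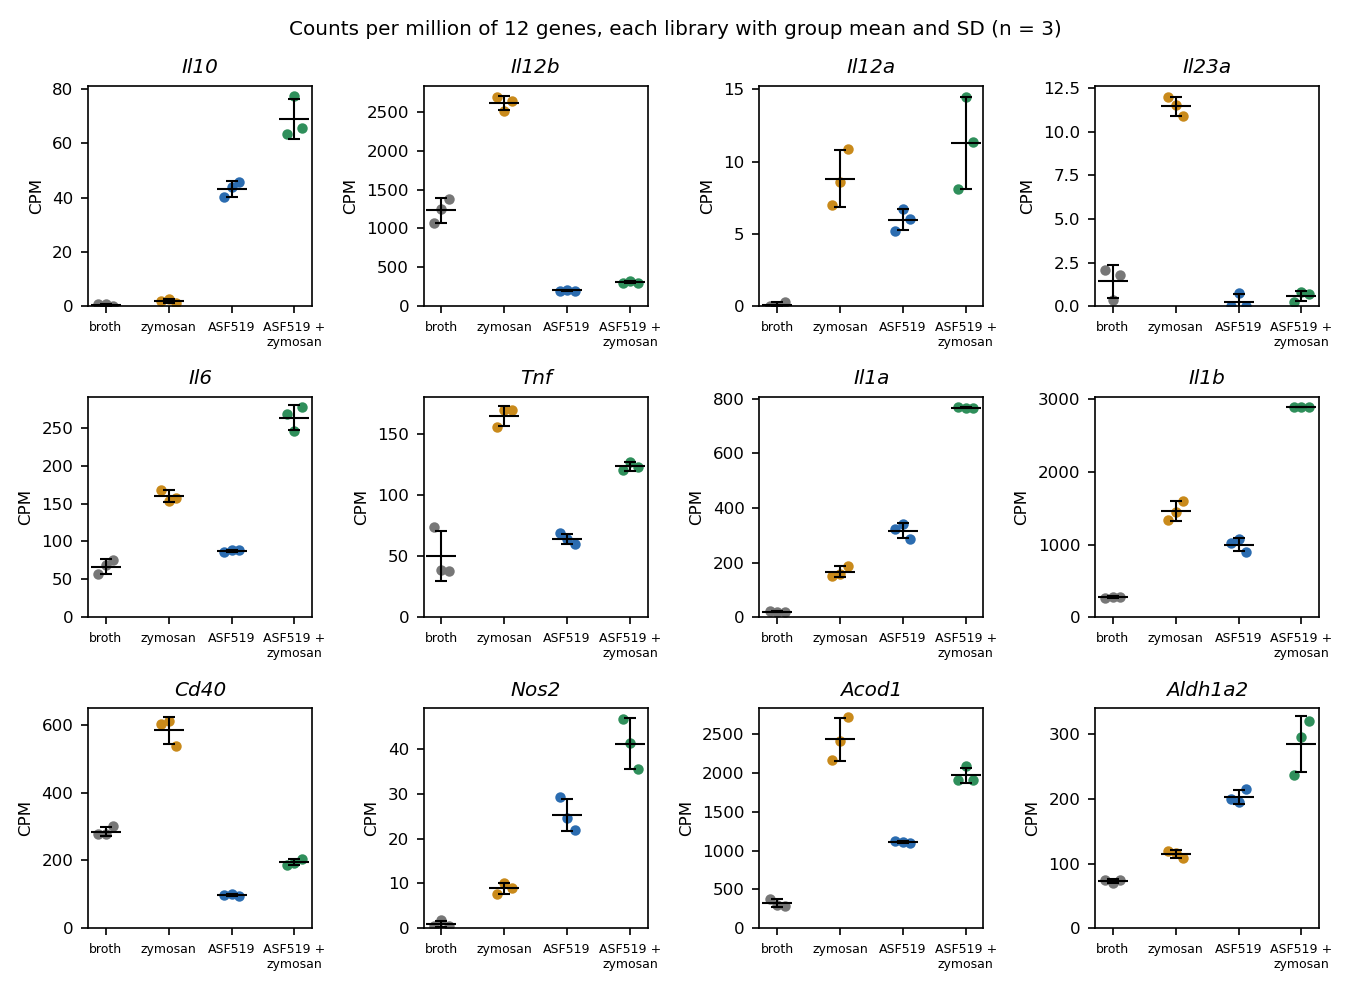
CPM of 12 genes of the fixed panel in each library (points, axes from 0), with the group mean and SD in black, n = 3 per group. Il10 lies at 43.3 ± 2.87 CPM in ASF519 and 0.535 ± 0.474 CPM in broth, and Il12b at 2612 ± 93.0 CPM with zymosan and 1234 ± 159 CPM in broth.

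ASF519 against broth shows what the spent medium changed in the absence of zymosan. Il10 rose from 0.535 ± 0.474 to 43.3 ± 2.87 CPM (n = 3), while Il12b fell from 1234 ± 159 to 204 ± 7.76 CPM and Cd40 from 285 ± 13.8 to 98.4 ± 2.07 CPM. Interleukin 1 genes rose as well, Il1a from 21.3 ± 2.94 to 318 ± 27.3 CPM and Il1b from 279.6 ± 8.78 to 997 ± 90.0 CPM. Lcn2 rose by log2 5.52 ± 0.10 (SE) and Nos2 by 4.65 ± 0.36. Has1, a hyaluronan synthase, rose by 7.13 ± 0.33, Inhba, an activin subunit, by 4.57 ± 0.18, and Serpinb2, a plasminogen activator inhibitor, by 4.27 ± 0.11.

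The test called 3356 genes, 1668 higher and 1688 lower in ASF519, and at least 2-fold 747 went up and 450 down. With the background expected from the unused families taken off each gene, which was tried after seeing the data, 3167 genes passed and 514 went up and 590 down at least 2-fold. With no filter on low counts 1164 went up at least 2-fold. Other large rises were Vnn3 (log2 7.66 ± 0.33), Cav1 (5.15 ± 0.15) and the triglyceride synthesis enzyme Dgat2 (4.57 ± 0.20). U90926 reached 247 counts over 3 libraries, a ratio to broth of 261 (95% counting interval 46.4 to 10349), and Il12a 54 counts, a ratio of 57.1 (95% counting interval 9.81 to 2295). The largest falls included Lad1 (log2 -5.12 ± 0.41), the endothelin receptor Ednrb (-4.70 ± 0.34), the cell fusion gene Dcstamp (-3.52 ± 0.28), Apoe (-3.40 ± 0.20), Igfbp4 (-3.30 ± 0.10) and Itgb8 (-3.23 ± 0.16), an integrin chain that activates latent TGF-beta. Rprm dropped from 120 counts over the 3 broth libraries to 2, 56.8-fold (95% counting interval 15.4 to 474) lower. The counts of Rprm, Lad1 and Ednrb left in ASF519 were no more than the background expected for their exons, which came to 181%, 141% and 106% of them. Tlr2 rose by 1.45 ± 0.12, the prostaglandin synthase gene Ptgs2 by 2.33 ± 0.22 and Aldh1a2, which makes retinoic acid, by 1.47 ± 0.11, and Clec7a fell by 1.21 ± 0.15. Tnf, Il1rn, Arg1 and Cd274 did not pass (adjusted p = 0.235, 0.336, 0.991 and 0.515). Without broth replicate 1, Tnf and Il1rn passed, at log2 0.73 and 0.42. Il23a did not pass either, with 14 counts over the 3 broth libraries and 2 in ASF519. It did pass, as lower in ASF519, in limma-voom, with the background taken off and without broth replicate 2 or ASF519 replicate 2 (log2 -5.43 to -2.23).

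Regulatory and tolerance-associated genes rose in 11 of 24 cases and fell in 3, with Il10 and the cytokine signalling inhibitor Socs3 (4.02 ± 0.13) at one end and Itgb8 at the other (adjusted p = 1.26e-07, 11 up and 4 down adjusted over the list alone). Maturation genes fell in 14 of 21 cases, with Il15ra at log2 -1.63 ± 0.14, and rose in 4, Cd86 by 0.71 ± 0.09 (adjusted p = 4.50e-07 and adjusted p = 0.0774 with an estimated correlation). The maturation list had 4 up and 15 down adjusted over the list alone. Class I antigen presentation genes fell in 11 of 16 cases and rose in 0, with Tapbpl at log2 -1.90 ± 0.14 and the immunoproteasome subunit Psmb10 at -1.68 ± 0.14 (adjusted p = 7.75e-07 and adjusted p = 0.0774 with an estimated correlation). They were 0 up and 12 down adjusted over the list alone. Class II genes rose in 8 of 14 cases and fell in 3, H2-DMb2 rising by 1.64 ± 0.13 and the protease Ctss at log2 -0.77 ± 0.08 (adjusted p = 0.00829 and adjusted p = 0.362 with an estimated correlation). The class II genes were 8 up and 3 down adjusted over the list alone. Chemokines rose in 9 of 16 cases, Ccl3 by 3.36 ± 0.19, and fell in 6, with Ccl6 at -2.64 ± 0.25 and Ccl17 at -2.49 ± 0.18 (adjusted p = 6.36e-11, 9 up and 6 down adjusted over the list alone). Ccl7 went from 2 to 27 counts, a ratio of 14.3 (95% counting interval 3.58 to 124). Inflammatory cytokines rose in 9 of 18 cases and fell in 4 (adjusted p = 0.0483 and adjusted p = 0.123 with an estimated correlation, 9 up and 5 down adjusted over the list alone). The cytokine list did not pass without broth replicate 1, 2 or 3 (adjusted p = 0.0742, 0.154 and 0.109, range over camera's alternatives 0.0251 to 0.154). Csf3 had 0 counts in broth and 25 in ASF519, at least 8.80-fold higher against the floor of 3 counts over the group.

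Inflammasome genes rose in 7 of 17 cases and fell in 2 (adjusted p = 8.95e-05, 7 up and 3 down adjusted over the list alone). Glycolysis and hypoxia genes rose in 16 of 28 cases and fell in 5, Ankrd37 rising by 2.90 ± 0.18 and Hk3 at -1.44 ± 0.12 (adjusted p = 3.90e-05 and adjusted p = 0.0774 with an estimated correlation). That list gave 17 up and 5 down adjusted over the list alone. Lysosomal genes fell in 19 of 28 cases and rose in 1, the acid lipase Lipa being at log2 -1.86 ± 0.08 (adjusted p = 4.22e-11 and adjusted p = 0.0774 with an estimated correlation). The lysosomal genes were 1 up and 19 down adjusted over the list alone. Pattern recognition genes fell in 14 of 25 cases and rose in 5, Clec4e by 2.22 ± 0.12 (adjusted p = 0.0374 and adjusted p = 0.0774 with an estimated correlation). The receptors were 5 up and 14 down adjusted over the list alone. Their list did not pass without ASF519 replicate 3 (adjusted p = 0.0546, range over camera's alternatives 0.00688 to 0.0774). Matrix remodelling genes rose in 10 of 22 cases, the proteoglycan Vcan by 2.87 ± 0.13, and fell in 6 (adjusted p = 1.83e-04 and adjusted p = 0.0774 with an estimated correlation). They gave 11 up and 6 down adjusted over the list alone. Macrophage markers fell in 10 of 17 cases and rose in 2 (adjusted p = 2.76e-06 and adjusted p = 0.0416 with an estimated correlation). These markers had 2 up and 10 down adjusted over the list alone. Neutrophil-associated genes rose in 7 of 9 cases and fell in 2, with Padi4 at -2.58 ± 0.59 and Csf3r at -1.54 ± 0.32 (adjusted p = 4.54e-09, 7 up and 2 down adjusted over the list alone). Transcripts encoded by mitochondria took 1.54% ± 0.112 of counts in ASF519 and 1.87% ± 0.0358 in broth.

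**Figure D3:**
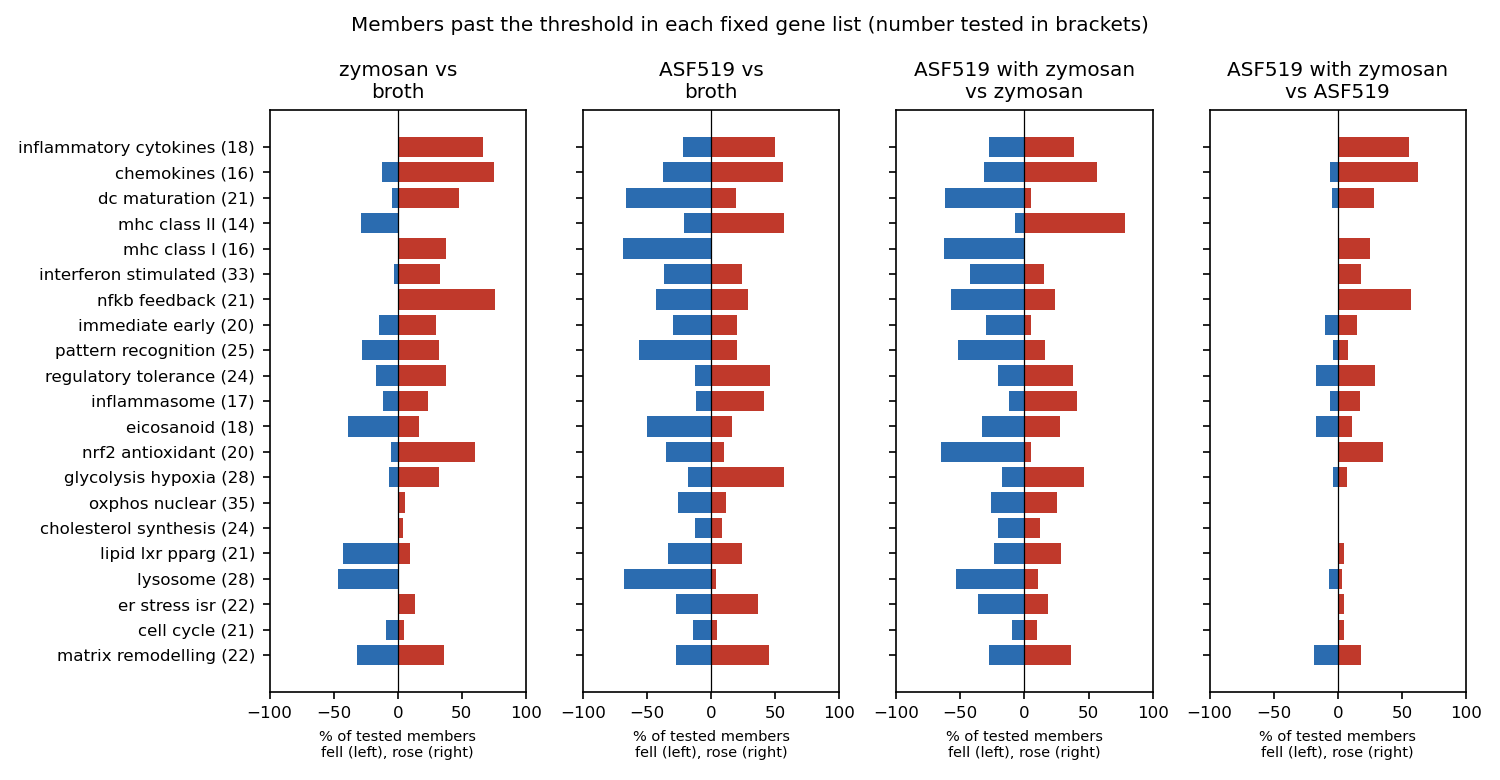
Percent of tested members that passed an adjusted p of 0.05 and rose (red, to the right) or fell (blue, to the left) in each of the 21 functional gene lists, for the 4 comparisons of 2 groups. Of 21 dendritic cell maturation genes 10 rose with zymosan in broth and 14 fell with the spent medium.

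ASF519 with zymosan against zymosan shows what the spent medium changed in zymosan-exposed cells. Il12b, at 2612 ± 93.0 CPM with zymosan (n = 3), fell by 3.08 ± 0.09 on the log2 scale, Il23a fell from 11.5 ± 0.544 to 0.600 ± 0.291 CPM and Cd40 from 583 ± 40.0 to 195 ± 9.58 CPM. Il10 rose from 1.92 ± 0.727 to 68.9 ± 7.37 CPM. Other inflammatory genes rose further, Il1a by log2 2.21 ± 0.09 (SE), Il1b by 0.99 ± 0.08, Il6 by 0.72 ± 0.09 and Ptgs2 by 2.20 ± 0.14, while the itaconate gene Acod1 fell by 0.30 ± 0.09. Without zymosan replicate 3 the change of Acod1 no longer passed, at log2 -0.22. Tnf and Il12a did not pass (adjusted p = 0.0602 and 0.321). Tnf passed in DESeq2, in limma-voom, with library size scaling, with no filter and in a fit of these groups alone, at log2 -0.49 to -0.39.

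Between these groups 3382 genes passed, 1608 higher and 1774 lower in spent medium, and at least 2-fold 609 went up and 485 down. With the background taken off, 3238 passed, and 424 went up and 543 down at least 2-fold. At least 2-fold, 932 went up with no filter and 400 with a stricter one. The largest rises beside Il10 included Has1 (log2 6.57 ± 0.24), Calm5 (3.52 ± 0.32), Vnn3 (3.52 ± 0.16), Inhba (3.34 ± 0.13), the monocyte chemoattractant Ccl2 (3.33 ± 0.26), Serpinb2 (3.24 ± 0.10) and U90926 (3.06 ± 0.12). The largest falls included Ednrb (-5.10 ± 0.37), Lad1 (-3.93 ± 0.25), the antiviral gene Oas2 (-3.56 ± 0.37), Dcstamp (-3.44 ± 0.26), the iron oxidase Heph (-3.39 ± 0.37), the sialic acid receptor Siglec1 (-3.26 ± 0.30) and Igfbp4 (-3.24 ± 0.10). Rprm dropped from 273 to 3 counts over 3 libraries, 69.8-fold (95% counting interval 23.6 to 340.5) lower. Expected background made up 109% of the counts of Ednrb left in spent medium, 87.3% of Rprm, 64.1% of Siglec1, 61.4% of Oas2 and 59.8% of Heph.

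Maturation genes fell in 13 of 21 cases and rose in 1 (adjusted p = 2.10e-09 and adjusted p = 0.0694 with an estimated correlation). They were 1 up and 14 down adjusted over the list alone. Class I genes fell in 10 of 16 cases and rose in 0 (adjusted p = 4.62e-06 and adjusted p = 0.0881 with an estimated correlation). The class I genes had 0 up and 10 down adjusted over the list alone. Class II genes rose in 11 of 14 cases and fell in 1 (adjusted p = 7.05e-08 and adjusted p = 0.0694 with an estimated correlation). The class II list had 11 up and 1 down adjusted over the list alone. Pattern recognition genes fell in 13 of 25 cases and rose in 4, the scavenger receptor Marco at -2.67 ± 0.20 and Tlr1 at -1.84 ± 0.15 (adjusted p = 7.54e-07, 4 up and 15 down adjusted over the list alone). Regulatory genes rose in 9 of 24 cases, Socs3 by 2.77 ± 0.10 and Ido1 by 1.66 ± 0.26, and fell in 5, with Itgb8 at -3.10 ± 0.14 (adjusted p = 7.54e-07, 12 up and 6 down adjusted over the list alone). Antioxidant genes fell in 13 of 20 cases and rose in 1, the malic enzyme Me1 being at -1.38 ± 0.29 (adjusted p = 1.12e-04 and adjusted p = 0.201 with an estimated correlation). This list had 1 up and 14 down adjusted over the list alone. Interferon-stimulated genes fell in 14 of 33 cases, with Ifi44 at log2 -3.20 ± 0.49, and rose in 5, Mx1 by 1.41 ± 0.09 (adjusted p = 0.00293 and adjusted p = 0.410 with an estimated correlation). Among these were 5 up and 16 down adjusted over the list alone. Chemokines rose in 9 of 16 cases and fell in 5, with Ccl17 at -2.73 ± 0.14 (adjusted p = 1.12e-04, 9 up and 5 down adjusted over the list alone). Inflammasome genes rose in 7 of 17 cases and fell in 2 (adjusted p = 5.78e-04, 7 up and 2 down adjusted over the list alone). Inflammatory cytokines rose in 7 of 18 cases and fell in 5, with a median log2 change above 0, a mean below it and a test pointing up (adjusted p = 0.893, not past the threshold, 8 up and 6 down adjusted over the list alone). Macrophage markers fell in 9 of 17 cases and rose in 1 (adjusted p = 2.00e-04 and adjusted p = 0.0694 with an estimated correlation). They had 1 up and 10 down adjusted over the list alone. Neutrophil-associated genes rose in 5 of 9 cases and fell in 2 (adjusted p = 0.00975 and adjusted p = 0.0816 with an estimated correlation). The neutrophil list had 5 up and 2 down adjusted over the list alone. Mitochondrially encoded genes fell in 4 of 10 cases and rose in 0 (adjusted p = 0.0375 and adjusted p = 0.410 with an estimated correlation). They were 0 up and 4 down adjusted over the list alone, and took 1.49% ± 0.136 of counts in ASF519 with zymosan and 1.78% ± 0.0514 with zymosan. The mitochondrial list did not pass without zymosan replicate 2 or 3 or ASF519 with zymosan replicate 2 (adjusted p = 0.0507, 0.0544 and 0.126, range over camera's alternatives 0.0177 to 0.410).

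The spent medium effects with and without zymosan, which share no library, were compared to see how alike they are. Both raised 966 genes, among them Has1, Il10, Inhba and Serpinb2, where independent lists would share 229. Both lowered 1100, among them Il12b, Cd40, Ednrb and Igfbp4, where independent lists would share 255, and 39 genes passed in opposite directions. Across the tested genes, which are not independent replicates, the log2 fold changes had a Spearman rho of 0.635. Both spent medium groups carry the higher background in unused families, so part of the shared rises and of rho may come from it. Expected background exceeded 25% of the counts for 261 of 1668 genes that rose without zymosan and 182 of 1608 with it. Among rises of at least 2-fold it did so for 253 of 747 and 178 of 609. The overlap and rho were not recomputed with the background taken off.

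**Figure D4:**
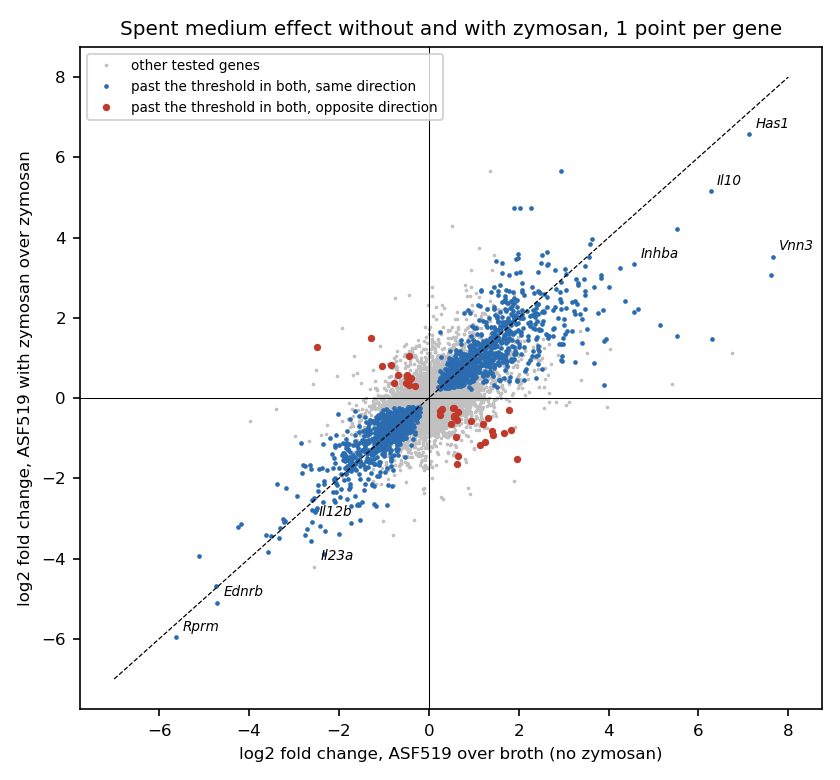
Log2 fold change of each tested gene in ASF519 over broth (horizontal) and in ASF519 with zymosan over zymosan (vertical), with genes past the threshold in both comparisons coloured by whether the directions are the same, and equal effects on the dashed line. Of the coloured genes 966 lie above 0 on both axes, 1100 below 0 on both, and 39 have opposite signs.

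ASF519 with zymosan against ASF519 shows what zymosan changed in cells kept in spent medium. Il6 rose from 87.8 ± 1.26 to 263 ± 16.2 CPM (n = 3), Il1b from 997 ± 90.0 to 2893 ± 6.04 CPM, Saa3 from 3129 ± 119 to 14008 ± 626 CPM and U90926 from 27.8 ± 2.00 to 261 ± 8.09 CPM. The acute-phase gene Hp, which encodes haptoglobin, rose by log2 2.40 ± 0.21 (SE), the arginine transporter Slc7a2 by 2.14 ± 0.10 and Ptges by 2.01 ± 0.15. The complement genes C1qc, C1qa and C1qb fell, at log2 -2.52 ± 0.33, -2.15 ± 0.13 and -1.71 ± 0.09, and Arg1 fell from 425 ± 60.5 to 104 ± 4.69 CPM.

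In this comparison 572 genes passed, 335 higher and 237 lower, and at least 2-fold 49 went up and 67 down. The number was 364 without ASF519 replicate 3 and 370 without ASF519 with zymosan replicate 2. Genes higher numbered 210 without ASF519 replicate 3, and genes lower 155 and 154 without ASF519 replicate 2 or 3 and 142 and 157 without ASF519 with zymosan replicate 2 or 3. In DESeq2 41 went down at least 2-fold. With the background taken off, 74 went up and 58 down at least 2-fold. Il12b rose by 0.60 ± 0.09, Il10 by 0.66 ± 0.14, Cd40 by 0.99 ± 0.09 and Acod1 by 0.83 ± 0.09. Other falls were the exchanger Slc9a9 (-2.16 ± 0.31) and the transcription factor Maf (-2.35 ± 0.31). Il12a did not pass (adjusted p = 0.0674) but did without ASF519 with zymosan replicate 1, at log2 1.12. Il23a did not pass either, with 2 counts in ASF519 and 6 in ASF519 with zymosan. Inflammatory cytokines rose in 10 of 18 cases and fell in 0 (adjusted p = 3.57e-32, 12 up and 0 down adjusted over the list alone). Chemokines rose in 10 of 16 cases, Cxcl10 by 3.92 ± 0.52, and fell in 1 (adjusted p = 1.33e-15, 10 up and 3 down adjusted over the list alone). NF-kB targets rose in 12 of 21 cases and fell in 0, the inhibitors Nfkbia and Tnfaip3 by 0.77 ± 0.08 and 0.82 ± 0.11 (adjusted p = 7.42e-15, 15 up and 0 down adjusted over the list alone). Macrophage markers fell in 5 of 17 cases and rose in 2 (adjusted p = 1.58e-12, 3 up and 7 down adjusted over the list alone). Maturation genes rose in 6 of 21 cases and fell in 1 (adjusted p = 1.38e-07 and adjusted p = 0.0990 with an estimated correlation). The maturation genes were 13 up and 2 down adjusted over the list alone. Neutrophil-associated genes rose in 4 of 9 cases and fell in 0 (adjusted p = 0.00162 and adjusted p = 0.0621 with an estimated correlation). The neutrophil genes were 4 up and 0 down adjusted over the list alone. Inflammasome genes rose in 3 of 17 cases and fell in 1 (adjusted p = 8.99e-05, 4 up and 1 down adjusted over the list alone). Class I genes rose in 4 of 16 cases and fell in 0 (adjusted p = 8.95e-06 and adjusted p = 0.124 with an estimated correlation). Antioxidant genes rose in 7 of 20 cases and fell in 0 (adjusted p = 3.19e-06 and adjusted p = 0.138 with an estimated correlation).

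Whether zymosan acted differently in the 2 media was tested by the interaction, the zymosan effect in spent medium minus that in broth. Lcn2 went from 83.1 ± 12.2 to 2011 ± 130.4 CPM with zymosan in broth and from 3816 ± 157 to 5930.1 ± 379.7 CPM in spent medium (n = 3), an interaction of log2 -3.96 ± 0.12 (SE). Acod1 (-2.08 ± 0.13), Il1a (-1.68 ± 0.16), Il1b (-0.85 ± 0.11) and Tlr2 (-1.13 ± 0.15) likewise had a smaller log2 effect of zymosan in spent medium. In CPM, Acod1 and Tlr2 gained less in spent medium than in broth, but Lcn2, Il1a and Il1b gained more, from a higher start. Apoe (3.14 ± 0.43) and Slc9a9 (2.79 ± 0.54), which fell with zymosan in broth, had a positive interaction. For Il10, Il6 and Cd40 the interaction did not pass (adjusted p = 0.545, 0.274 and 0.934).

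The interaction passed for 413 genes, 159 positive and 254 negative, and for 184 of them it was at least 2-fold. In the simulated counts 10 of 93 interaction calls were false. Of the 1699 genes changed by zymosan in broth 368 passed, and in 367 of these the interaction opposed the effect in broth. The broth and zymosan libraries enter both values, so shared chance values also push them apart. Chemokines had 1 positive and 5 negative interactions among 16 genes, the neutrophil attractant Cxcl5 at -1.92 ± 0.13 (adjusted p = 9.63e-09, 2 up and 7 down adjusted over the list alone). Pattern recognition genes had 3 positive and 5 negative ones of 25, Mrc1 at 3.22 ± 0.61 and Clec4e at -2.06 ± 0.16 (adjusted p = 6.71e-04, 3 up and 7 down adjusted over the list alone). Lipid target genes had 5 positive and 2 negative of 21 (adjusted p = 0.00211, 7 up and 3 down adjusted over the list alone). Neutrophil-associated genes had 0 positive and 3 negative of 9 (adjusted p = 1.62e-11, 1 up and 4 down adjusted over the list alone). Lysosomal genes had 9 positive and 0 negative of 28 (adjusted p = 9.63e-09 and adjusted p = 0.180 with an estimated correlation). The lysosomal interactions were 13 up and 1 down adjusted over the list alone. Inflammatory cytokines had 0 positive and 4 negative of 18 (adjusted p = 0.00160 and 0.0535 with an estimated correlation). In this order, NF-kB targets had 0 and 2 of 21 (adjusted p = 0.0101 and 0.180). Glycolysis and hypoxia genes had 0 and 3 of 28 (adjusted p = 0.00357 and 0.180), and class II genes 3 and 0 of 14 (adjusted p = 0.00201 and 0.272). Ribosomal protein genes had 0 positive and 0 negative of 33 with a test pointing up (adjusted p = 0.00389 and adjusted p = 0.626 with an estimated correlation), and 0 up and 0 down adjusted over the list alone. Their list did not pass without zymosan replicate 2 (adjusted p = 0.105, range over camera's alternatives 2.88e-06 to 0.626).

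**Figure D5:**
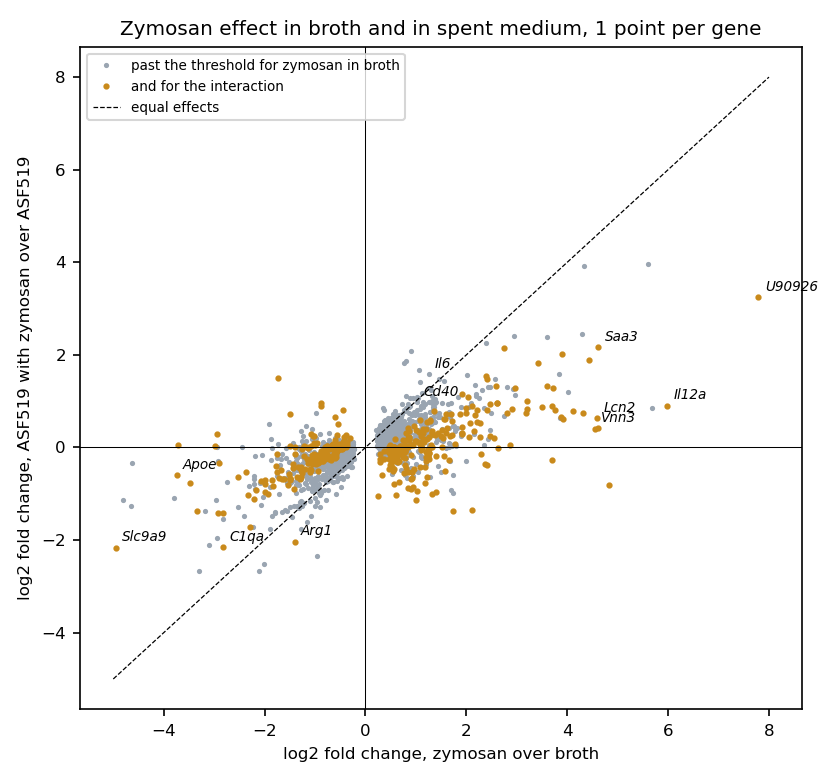
Log2 fold change by zymosan in broth (horizontal) and in spent medium (vertical) for the 1699 genes changed by zymosan in broth, with genes past the interaction test in a separate colour and equal effects on the dashed line. Of the 368 genes past the interaction test 367 have an interaction opposite in sign to their effect in broth.

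Among the 1699 genes that zymosan changed in broth, the spent medium moved 532 the opposite way in zymosan-exposed cells and 393 further the same way. In 10 simulations without a spent medium effect, where almost no gene passed for the spent medium, these numbers had means of 0.5 and 0.3, which says nothing about the split between directions. Genes raised by zymosan and lowered by the spent medium numbered 362, among them Il12b, Il23a, Cd40, Acod1 and Marco, where independent lists would share 139.8. Genes lowered by zymosan and raised by the spent medium numbered 170, Ccr2 among them, where independent lists would share 106. Changes the same way were 179 raised by both, where independent lists would share 127, and 214 lowered by both, where they would share 117. The zymosan libraries enter both comparisons, so part of the excess in opposite directions may come from them.

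Zymosan and the spent medium, each against broth, were compared to see how alike their effects are. Both raised 378 genes, among them Lcn2, Saa3, Il1a, Il1b and Nos2, and both lowered 432, among them Apoe, C1qa and Ccl6. In opposite directions 191 genes passed, Il12b and Cd40 among them. Independent lists would share 131 raised and 112 lowered genes. Spearman's rho across genes, which are not independent replicates, was 0.325, against means of 0.485 in simulations with neither effect and 0.245 in simulations with the zymosan effect alone, both with shared broth libraries. It lies between these values. The covariance was 0.151 against 0.0331 with neither effect, a difference of 0.118 with a jackknife SE of 0.104 over the 12 libraries, computed after the result was seen. Without broth replicate 3 the covariance was 0.242. The 3 broth libraries could not be split into sets of at least 2, so part of the excess in covariance and overlap may come from the shared controls.

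In the mm10 genome the GENCODE M21 annotation places Il10 on chromosome 1, 131019845 to 131024974, plus strand, Il12b on chromosome 11, 44400063 to 44414033, plus strand, Il23a on chromosome 10, 128296139 to 128298752, minus strand and Lcn2 on chromosome 2, 32384633 to 32388252, minus strand. Cd40 lies on chromosome 2, 165055627 to 165072948, plus strand and Has1 on chromosome 17, 17843323 to 17855205, minus strand. All are protein-coding, and their counts are taken as counts over exons. Exons of Il1a, Il1b, Cxcl10, Lox, Maf, Acsl1, Ankrd37, Cd274, Heph, Hk3, Me1, Slc7a2, Tbxas1 and Hsp90b1 overlap genes on the other strand, and those of Serpinb2 and Hsp90b1 genes on the same strand. Whether counting used strand is not given in the sources used here, so their values are uncertain to that extent.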

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

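The thinning test of the number of detected genes was chosen only after the result was seen, as were the subtraction of background and the handling of S100a9 by raw counts. The zymosan effect differed between the media, by the interaction test, for 413 genes. The lipoprotein gene Apoe, the exchanger Slc9a9, Slc26a9 and Rab3il1, which fell with zymosan in broth, had positive interaction log2 values of 3.14, 2.79, 1.84 and 1.84. The strongest negative values among abundant genes were -4.55 for U90926, -4.14 for Vnn3, -3.96 for Lcn2, -3.58 for Lox and -3.33 for Cav1. In the fixed panel the test passed for Il12a (-5.07), Nos2 (-2.44), Acod1 (-2.08), Il1a (-1.68), Tlr2 (-1.13), Il1b (-0.85), Arg1 (-0.63) and Il12b (-0.48). Arg1 fell with zymosan in broth, so its negative value means a larger fall in spent medium. The others rose in broth, so theirs mean smaller rises on the log2 scale, as ratios. In CPM, Il12a, Il12b, Acod1 and Tlr2 also gained less in spent medium, but Il1a, Il1b and Nos2 gained more, from a higher start. Il1a was at 18.6 to 24.4 CPM in broth and 152 to 189 CPM with zymosan. In spent medium it was at 288 to 341 CPM in ASF519 and 765 to 769 CPM in ASF519 with zymosan. Calls were lost for Arg1 without zymosan replicate 2 or 3 or ASF519 with zymosan replicate 2 (-0.52, -0.58 and -0.58), and for Il12b without zymosan replicate 1, ASF519 replicate 2 or ASF519 with zymosan replicate 3 (-0.44 each). U90926 and Il12a had 1 count each over the 3 broth libraries, so the size of their fitted values depends on the prior count. Among 100 splits of the 12 libraries, the real one included, 1 gave as many genes, and the highest of the others gave 374. Shuffled labels carry part of the main effects, so the other splits are not free of real differences. Shuffled groups also mix libraries that differ by the main effects, which widens the spread within groups and holds down calls. The splits therefore cannot say whether chance alone could give this interaction.

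The smaller zymosan response in spent medium, in number of genes and on the log2 scale, was weighed against 3 explanations. A difference in depth is argued against, since with all libraries thinned to the smallest total 1367 genes still passed in broth and 493 in spent medium, 2.77 times as many. Background reads are argued against only as far as their density per kb of exon is even over genes, which is not shown. The slope of the effect in spent medium on that in broth was 0.321 before and 0.359 after the background was taken off. Simulations with additive effects, with no background taken off, gave at least 0.835. These simulations took the fitted group means as true, and 2225 to 2380 genes passed for zymosan in broth, against 1699 in the data. The simulated slopes in this paragraph may therefore be too high. That genes already moved the same way by the spent medium respond less stays open, as a hypothesis: their slope was lower by 0.0890 than that of genes it did not move, and simulations gave at most 0.0234, while with the background taken off the slopes were 0.277 and 0.456. It may cover only part, as genes not moved had a slope of 0.368 against at least 0.826 in simulations, and genes the spent medium moved the opposite way had 0.471 (0.622 with the background taken off) against 0.827 to 0.996 in simulations.

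More gene symbols had counts in the spent medium libraries. Depth is argued against, since after thinning to the smallest total the 6 spent medium libraries had 5269.5 more on average. Reads from genomic DNA or unspliced RNA stay open as a candidate explanation: unused gene families were higher in each spent medium library than in each other one, by at least 1.68 times. Their density per kb of exon had a ratio of 1.08 (95% counting interval 1.05 to 1.11) between olfactory receptors and the other families. The other families are mostly vomeronasal receptors, 1797 of 1925 kb, and small families differed. In ASF519 replicate 3, keratin-associated genes had 16 counts over 49.4 kb, trace amine receptors 9 over 15.8 and defensins 17 over 29.0. Taste receptors had 57 over 34.1 kb and olfactory receptors 3982 over 3632 kb. An even density over all families is thus not shown. The source of such reads was not tested, and a biological effect of the spent medium on the cells stays untested too.

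Neutrophil-associated genes rose in 7 of 9 cases in ASF519 against broth, out of 18 listed, and 1 of those tested, Mmp8, is also in the matrix list. Neutrophils in the culture would bring all their abundant transcripts. Lcn2 rose by log2 5.52, while the median of the other 8 tested members was 1.19, which is 4.33 lower. S100a8 rose by 1.45, and S100a9, with too few counts to be tested, had 8 counts in broth and 4 in ASF519, a ratio of 0.542 (95% counting interval 0.119 to 2.02). These values argue against neutrophils as the source of the rise of Lcn2. For the smaller rises of the other members the few counts of S100a9 speak against neutrophils. So do the falls of 2 list members, Padi4 and Csf3r. As the other 7 of 9 rose, that source stays open for the smaller rises. Expression of single members by the cultured cells stays open and untested.

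The 6 libraries of each comparison of 2 groups allow 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave the largest number. The real and highest other numbers were 1699 and 0 for zymosan against broth, 3356 and 0 for ASF519 against broth, 3382 and 0 for ASF519 with zymosan against zymosan, and 572 and 1 for ASF519 with zymosan against ASF519.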

How the results depend on the processing

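The fits without satellite-like symbols, with protein-coding genes alone and with the background taken off were chosen only after the results were seen. In the order zymosan against broth, ASF519 against broth, ASF519 with zymosan against zymosan, ASF519 with zymosan against ASF519, and interaction, 506, 1197, 1094, 116 and 184 genes also changed at least 2-fold, fewer by construction. With an estimated correlation 8, 5, 4, 5 and 4 lists passed, and with fry, which tests a list against no change and not against other genes, 20 for ASF519 against broth, and the cause was not tested. Leaving out 1 library gave 364 to 539 genes for ASF519 with zymosan against ASF519, with fewer samples, the lowest without ASF519 replicate 3, and 370 without ASF519 with zymosan replicate 2. Without a filter 65.3% of calls were higher with zymosan in broth, against 54.4%, and 69.9% in spent medium, against 58.6%. Without 1 library the higher genes for ASF519 with zymosan against ASF519 numbered 210 against 335 and the lower genes 142 against 237 at the lowest, without ASF519 replicate 3 and ASF519 with zymosan replicate 2. Genes at least 2-fold higher numbered 1164 with no filter against 747 for ASF519 against broth, and 932 with no filter and 400 with a stricter one against 609 for ASF519 with zymosan against zymosan. For ASF519 with zymosan against ASF519, genes at least 2-fold lower numbered 41 in DESeq2 against 67, and those at least 2-fold higher 74 with the background taken off against 49. No named gene or list past the threshold in both fits changed direction. Of 535 gene results 84 lost their call without some library and 64 under another setting. Replicate numbers did not pair the samples: the 18 same-number pairs correlated by -0.133 to 0.0577, and 0 of 12 libraries correlated best with their own number. With replicate number as a block 1600, 3206, 3225, 519 and 360 genes passed. Under this block Il12a passed for ASF519 with zymosan against ASF519, at log2 0.95, and the cytokine list did not for ASF519 against broth (adjusted p = 0.0514, range over camera's alternatives 0.0251 to 0.154). DESeq2 gave no adjusted p for 2501 genes in ASF519 with zymosan against ASF519 and 910 in the interaction. Depth limits genes with few counts, such as Il23a, with 2 counts over the 3 ASF519 libraries.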

Other observations

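The tests of gene lists were all planned, and no test in this part was chosen after the results were seen. Phgdh, the first enzyme of serine synthesis, rose by log2 3.32 ± 0.59 (SE, n = 3) in ASF519 against broth, while the endoplasmic reticulum chaperones Hsp90b1 and Hspa5 fell, at -0.85 ± 0.09 and -0.72 ± 0.08. The endoplasmic reticulum stress list, which holds these genes, had 8 rises and 6 falls of 22 (adjusted p = 0.790, not past the threshold, 8 up and 8 down adjusted over the list alone). Among eicosanoid genes Ptges rose by 2.39 ± 0.23 and the thromboxane synthase Tbxas1 fell by 1.65 ± 0.12, with 3 rises and 9 falls of 18 (adjusted p = 0.345, not past the threshold, 5 up and 9 down adjusted over the list alone). Immediate early genes had 4 rises, Ier3 by 2.26 ± 0.11, and 6 falls of 20 (adjusted p = 0.790, not past the threshold, 4 up and 6 down adjusted over the list alone), with a median and mean just above 0 and a test pointing down. Among dendritic cell markers Itgax, which encodes CD11c, was at -1.56 ± 0.10 and the transcription factor Irf4 rose by 1.44 ± 0.15, with 4 rises and 3 falls of 15 (adjusted p = 0.903, not past the threshold, 4 up and 4 down adjusted over the list alone). Here too the median and mean lay above 0 and the test pointed down.

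In the same comparison nuclear oxidative phosphorylation genes had 4 rises and 9 falls of 35 (adjusted p = 0.139, not past the threshold, 4 up and 9 down adjusted over the list alone). Without broth replicate 3 or ASF519 replicate 1 this list passed (adjusted p = 0.0263 and 0.0420, range over camera's alternatives 0.0263 to 0.829). Cholesterol synthesis genes had 2 and 3 of 24 (adjusted p = 0.660, not past the threshold, 2 up and 2 down adjusted over the list alone), with a median above 0 and a mean and test below it, and cell cycle genes 1 and 3 of 21 (adjusted p = 0.345, not past the threshold, 1 up and 3 down adjusted over the list alone). Ribosomal protein genes had 3 and 5 of 33 (adjusted p = 0.300, not past the threshold, 3 up and 5 down adjusted over the list alone), and mitochondrially encoded genes 0 and 5 of 10 (adjusted p = 0.0702, not past the threshold, 0 up and 5 down adjusted over the list alone). The latter passed without broth replicate 3 or ASF519 replicate 1 (adjusted p = 0.0461 and 0.0420, range over camera's alternatives 0.0420 to 0.539). Monocyte markers had 1 and 6 of 9 (adjusted p = 0.901, not past the threshold, 1 up and 6 down adjusted over the list alone) and eosinophil markers 1 and 1 of 3 (adjusted p = 0.790, not past the threshold, 2 up and 1 down adjusted over the list alone). Too few members were measured to test mast cell or basophil markers (2 of 13), T and NK cell markers (1 of 16), B and plasma cell markers (2 of 12) and erythroid markers (0 of 12).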
